A study of Mus musculus with 8 samples.

How the data were processed

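The deposited table held raw counts per gene for 8 libraries, which the authors made, per the labels, with Trim Galore 0.6.4, cutadapt 2.10, STAR 2.7.3a and featureCounts 2.0.1 on the mouse build GRCm38.p6. Strandedness, the treatment of reads with several positions, duplicate removal and the annotation release are not given in the sources. The 8 columns were mapped to CaMKIIβ RIP (3), IgG RIP (3) and Input (2) by their names, and 0 columns were left unmapped.

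Genes carried Ensembl identifiers and coordinates without symbols. Symbols and gene classes came from RefSeq genes on GRCm38.p6, each joined to the gene that shared at least 0.5 of their joint span, without regard to strand, when each was the best partner of the other and no second partner reached 0.8 of that share. This rule was chosen after the table was seen. It named 34134 of 55401 genes, which held 96.1% of counts, among them 3725 long noncoding and 19186 protein-coding genes, with a median shared fraction of 0.995. The 21267 genes without a match held 3.85% of counts and were tested without a class, so long noncoding genes among them are not in the class counts.

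Each of the 3 comparisons was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15). Genes with a Benjamini-Hochberg adjusted p under 0.05 were past the threshold. The replicate number was not used as a block, since the labels do not say that libraries with the same number share animals. Where the block was tried against Input, RIP replicate 3 had no Input of its number and did not bear on the difference. The 24 gene lists were fixed from prior knowledge before the counts arrived and were tested with camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Members were also adjusted over the list alone. CPM are counts scaled to a common library size by TMM within the comparison, given as group means ± SD, and log2 fold changes carry the SE. Class shares were compared by a two-sided exact permutation test. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

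The genes to be named were set by a rule before the counts arrived. It took the CaMKII subunits, the largest changes past the threshold among genes with an average log2 CPM of at least 1 and libraries that did not overlap, the 5 long noncoding RNA genes with the smallest p where fewer passed, and up to 4 members of a described list. All 24 lists were tested in all 3 comparisons, and which of them are described at length was chosen after the values were seen.

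The alternatives tried were RLE, upper quartile and library size scaling, TMM without mitochondrial and structural RNA, no count filter, at least 10 counts in every library of a group, DESeq2 1.42.0, limma-voom, a fit of all 8 libraries, the replicate block, a fold change of at least 2 and each library left out. A span match of at least 0.8 and the removal of a trend on exon length (loess span 0.5) were added after the data were seen, as was a comparison of each antibody with an Input library of its own. The test was run on simulated counts with 200 changed genes, in which it called 6, 9 and 8 unchanged genes in CaMKIIβ RIP against IgG RIP, CaMKIIβ RIP against Input and IgG RIP against Input. In the last 2 comparisons it recovered 30% and 86% of 2-fold changes. The changed genes were drawn from those with an average log2 CPM of at least 1, and each gene had the same spread in all libraries. No library was left out of the fits reported first. GC content was not examined, since no genome sequence was at hand.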

Results

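RNA immunoprecipitation (RIP) recovers a protein from a lysate with an antibody, together with the RNA that comes along with it. RIP libraries from C57BL/6 mouse tissue labelled hippocampus were sequenced in this series, and cerebellar transcripts were abundant in all of them, so that the cell types behind a gene list are not certain. Expression was measured as deposited raw counts per gene. The 8 libraries formed 3 groups: 3 RIP libraries made with an antibody against CaMKIIβ, 3 RIP libraries made with control IgG, and 2 Input libraries of RNA that was not immunoprecipitated. CaMKIIβ, encoded by Camk2b, is a subunit of calcium/calmodulin-dependent protein kinase II, an abundant kinase of excitatory synapses. Replicates 1, 2 and 3 held 25299903, 17273957 and 21406489 counts in CaMKIIβ RIP, and 22768460, 22061623 and 28138289 in IgG RIP. The Input libraries held 17776157 and 21359418. At least 1 count was seen for 27064, 19247 and 24865 genes in CaMKIIβ RIP, for 28458, 27724 and 27380 genes in IgG RIP, and for 30899 and 31152 genes in Input. CaMKIIβ RIP replicate 2 stood apart from the other libraries. On the first principal component, which held 49.7% of the variance, it scored -95.4, and the other 7 libraries lay between -2.24 and 38.0. Of the genes expected to have 20 to 50 counts from the other RIP libraries, 28.3% had 0 counts in this library, against at most 1.71% in any other RIP library. CaMKIIβ RIP replicate 2 was left out of the expectation for each of the others too. CaMKIIβ RIP replicate 3 also lay apart, at -48.6 on the third principal component (11.6% of the variance), against -1.15 to 11.8 elsewhere. By chi-square per gene, a distance between 2 libraries, CaMKIIβ RIP replicate 1 lay 8.35 to 12.4 from the IgG RIP libraries. It lay 48.8 and 31.05 from CaMKIIβ RIP replicates 2 and 3. Distances among the IgG RIP libraries were 6.11 to 13.96. The CaMKIIβ RIP libraries thus did not form a group of their own by this distance.

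**Figure D1:**
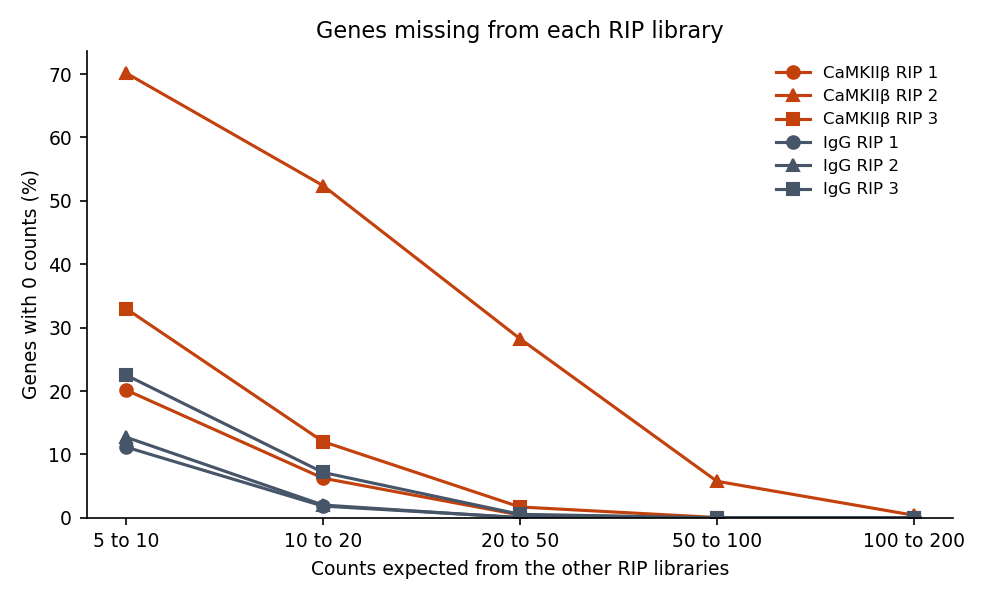
Percent of genes with 0 counts (y axis) in each of the 6 RIP libraries, by the number of counts expected from the other RIP libraries (x axis). CaMKIIβ RIP replicate 2 was left out of every expectation, and each line is 1 library. CaMKIIβ RIP replicate 2 lacked 28.3% of the genes with 20 to 50 expected counts, and the other libraries lacked 1.71% at most.

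The series title names long noncoding RNAs bound by CaMKIIβ as its subject. CaMKIIβ RIP against IgG RIP asks which RNAs were at a higher scaled level with the CaMKIIβ antibody than with the control antibody. Levels were scaled to library size, so a difference between the antibodies in the total amount of RNA recovered cannot be seen. The transcripts of the kinase itself were at like scaled levels with both antibodies. Camk2b (ENSMUSG00000057897.14, GRCm38 chromosome 11, 5969644 to 6066362) reached 983 ± 113 CPM (counts scaled to library size; SD, n = 3) with CaMKIIβ and 1001 ± 63.8 (n = 3) with IgG, a log2 fold change of -0.03 ± 0.10 (SE). Camk2a (ENSMUSG00000024617.16), which encodes the partner subunit α, reached 1560 ± 213 and 1564 ± 99.6 CPM, a 95% interval from -0.24 to 0.24 on the log2 scale. The log2 fold changes were 0.07 ± 0.09 for Camk2d and -0.02 ± 0.11 for Camk2g. All 4 had adjusted p from 0.982 to 0.999, and no direction is given for them.

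Among 1130 long noncoding RNA genes tested, 0 differed between the antibodies, over all genes tested and when adjusted over long noncoding RNA genes alone. An unadjusted p under 0.05 was reached by 23, where chance gives 56.5. Without CaMKIIβ RIP replicate 1, 2 or 3 this count was 132 of 1240, 80 of 1267 and 35 of 1239 genes tested. Without IgG RIP replicate 1, 2 or 3 it was 6, 5 and 10. The count thus depended on the libraries used and does not show that the antibodies were more alike than chance. With all libraries, the 5 long noncoding RNA genes with the smallest p, not past the threshold, included Zmiz1os1 (ENSMUSG00000087535.2, chromosome 14, 25257523 to 25461128). Its log2 fold change was 0.57 ± 0.21 (SE, n = 3 and 3). Gm8098 had a log2 fold change of 1.09 ± 0.40, 4933412E12Rik one of 1.55 ± 0.57 and B930059L03Rik one of 1.63 ± 0.60. For 4933431E20Rik the value was -0.62 ± 0.22, and each of the 5 had an adjusted p of 0.982. The paternally expressed antisense transcript Kcnq1ot1 was at 163 ± 30.4 and 154 ± 8.89 CPM (SD, n = 3 each), and the imprinted Snhg14 at 326 ± 81.3 and 310 ± 29.2. The 95% interval lay below a 2-fold excess in CaMKIIβ RIP for 320 of the 1130 genes, and within 2-fold on both sides for 139. A 2-fold excess was thus not excluded for the other long noncoding RNA genes. The libraries of the antibodies lay apart for 11.8% of these genes, where chance gives 10%.

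Over all 20566 genes tested with edgeR, 0 differed, and the smallest adjusted p was 0.982. An unadjusted p under 0.05 was found for 721 genes, where chance gives 1028. DESeq2 called 0 genes and gave 907 such p values, and limma-voom called 0 and gave 780. The CaMKIIβ RIP libraries lay on 1 side of the IgG RIP libraries for 12.1% of genes, where chance gives 10%. On simulated counts the test recovered 38% of 2-fold, 74% of 4-fold and 98% of 8-fold changes. The changed genes had an average log2 CPM of at least 1, as did 489 of the 1130 long noncoding RNA genes. Each simulated gene had the same spread in all libraries, unlike the real data, where CaMKIIβ RIP replicate 2 stood apart. Recovery in the real data may thus be lower. The 95% interval lay within 2-fold for 9846 of 14059 protein-coding genes. Without CaMKIIβ RIP replicate 2 the common biological coefficient of variation fell from 0.388 to 0.243, and the count of differing genes was again 0, with 1222 unadjusted p values under 0.05. Without CaMKIIβ RIP replicate 1 or 3 there were 2592 such values among 21544 genes and 1281 among 21567. Without IgG RIP replicate 1, 2 or 3 there were 204, 251 and 255, and each of these fits had 0 genes past the threshold. Chance gives a share of 0.05, and the share was above that without any CaMKIIβ RIP library and below it without any IgG RIP library.

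**Figure D2:**
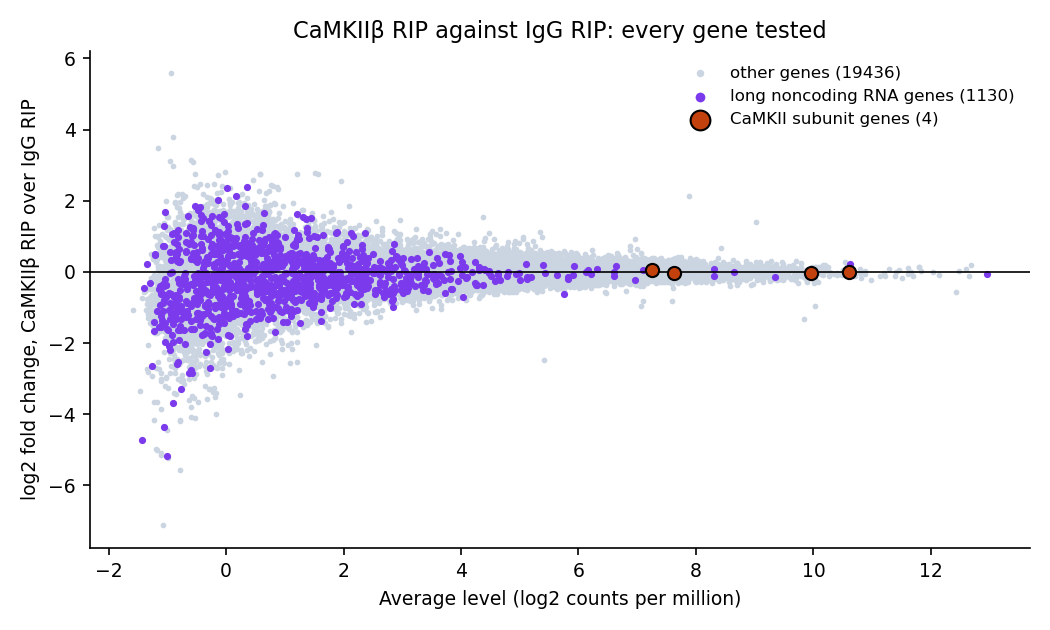
Log2 fold change of CaMKIIβ RIP over IgG RIP (y axis) against average level in log2 CPM (x axis) for the 20566 genes tested; each point is a gene, with 1130 long noncoding RNA genes and the 4 CaMKII subunit genes picked out. The subunit genes lie between -0.03 and 0.07, and 0 genes passed the threshold.

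In the same comparison 3 of 24 fixed gene lists moved as a group, with 0 members past the threshold in any of them. The 17 mitochondrially encoded genes tested were shifted down (median log2 fold change -0.57, adjusted p = 0.00401 by camera, 0.716 with an estimated correlation). Among them mt-Cox1, a subunit of cytochrome c oxidase, was at 4421 ± 1278 against 6579 ± 533 CPM, and mt-Cytb at 141 ± 47.7 against 247 ± 6.93 (SD, n = 3 each). The 78 cytosolic ribosomal protein genes were shifted up (median 0.14, adjusted p = 1.8e-04, and 0.47 with an estimated correlation), with Rps16 at 0.71 ± 0.23, Rpl18 at 0.81 ± 0.29, Rps27a at -0.42 ± 0.18 and Rpl23a at -0.87 ± 0.48 (log2 fold change ± SE). The 80 nuclear-encoded genes of oxidative phosphorylation were also shifted up (median 0.12, adjusted p = 0.00194, and 0.47 with an estimated correlation), with Cox6a1 at 0.80 ± 0.27, Atp5mpl at 0.75 ± 0.25, Ndufv3 at -0.39 ± 0.20 and Uqcrb at -0.45 ± 0.25. Without CaMKIIβ RIP replicate 2, in which mitochondrially encoded genes took 0.36% of counts against 0.648% and 0.656% in its group, 0 lists passed and each of these 3 had an adjusted p of 0.148. Without CaMKIIβ RIP replicate 1 the mitochondrial list no longer passed (adjusted p = 0.115) and blood markers did (0.0325), as they did without IgG RIP replicate 1 (0.0349). Without CaMKIIβ RIP replicate 3, 5 lists passed, the list of neuronal and nuclear long noncoding RNAs among them (adjusted p = 0.0346). With all libraries the other 21 lists had adjusted p from 0.116 to 0.9999. Among blood markers 0 of 8 members were past the threshold over all genes, and 1 was when adjusted over the list alone. That gene, Hbb-bs, encodes a β-globin and was at 156 ± 42.2 against 99.3 ± 9.68 CPM (n = 3 each). The CaMKII regulators and partners held Camk2n2, an inhibitor of the kinase, at 0.88 ± 0.29, Camkk1 at 0.29 ± 0.15, Camk1 at -0.27 ± 0.18 and Ppp1ca at -0.22 ± 0.17, and 0 of their 17 members passed.

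CaMKIIβ RIP against Input asks which RNAs were more or less abundant in the immunoprecipitate than in Input RNA; the labels do not say which Input belongs to which immunoprecipitate. Members of fixed lists of postsynaptic scaffolds, dendritic mRNAs and astrocyte markers were among the genes that rose, and mitochondrial transcripts and neuronal and nuclear long noncoding RNAs among those that fell. Bsn, a scaffold of the presynaptic active zone, rose 2.43-fold, from 812 ± 20.9 to 1973 ± 70.4 CPM (SD, n = 2 Input and n = 3 RIP, as in the rest of this comparison). Mbp, a structural protein of myelin, rose 3.35-fold, from 1791 ± 68.9 to 5993 ± 584 CPM. The cytochrome b transcript mt-Cytb was 8.48-fold lower, at 147 ± 49.9 against 1250 ± 12.4 CPM.

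Of the 4 CaMKII subunit genes, Camk2a (log2 fold change 1.04 ± 0.14, SE) and Camk2b (0.53 ± 0.12) rose, Camk2d (-0.47 ± 0.11) fell, and Camk2g (0.40 ± 0.12) did not pass; 3 were higher and 1 lower when adjusted over the list alone, and the list had an adjusted p of 0.0378 (0.302 with an estimated correlation). Of 19 postsynaptic density scaffold genes, 9 rose and 0 fell (12 and 2 adjusted over the list alone; list adjusted p = 3.05e-12, and 0.174 with an estimated correlation), with Shank3 at 1.21 ± 0.11 and with Homer1 at -0.50 ± 0.15 and Dlg1 at -0.34 ± 0.12 not past the threshold. Of 20 dendritically localized mRNAs, 12 rose and 0 fell (13 and 1 adjusted over the list alone; list adjusted p = 5.96e-14, and 0.174 with an estimated correlation), among them the calcium channel Itpr1 (1.37 ± 0.11) and the motor protein Kif1a (1.51 ± 0.13). Of 15 ionotropic glutamate receptor genes, 6 rose and 0 fell (8 and 3 adjusted over the list alone; list adjusted p = 0.0031, and 0.269 with an estimated correlation), with the NMDA receptor subunit Grin1 at 0.92 ± 0.11 and the kainate receptor subunit Grik5 at 0.84 ± 0.14. The AMPA receptor subunits Gria2 (-0.87 ± 0.24) and Gria3 (-0.45 ± 0.12) did not pass over all genes. Presynaptic vesicle genes gave 4 higher and 1 lower of 18 (7 and 1 adjusted over the list alone; list adjusted p = 0.00448, and 0.28 with an estimated correlation). With library size alone as the scaling these were 1 higher and 2 lower, and the subunits 1 and 1. Of 12 astrocyte markers, 7 rose and 0 fell (10 and 0 adjusted over the list alone; list adjusted p = 5.4e-11, and 0.174 with an estimated correlation), among them the glutamate transporter Slc1a2 (1.33 ± 0.11) and the filament protein Gfap (1.09 ± 0.12). Of 15 oligodendrocyte lineage markers, 5 rose and 1 fell (6 and 3 adjusted over the list alone; list adjusted p = 6.52e-04, and 0.174 with an estimated correlation), with the progenitor proteoglycan Cspg4 at 1.85 ± 0.15.

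Of the 751 genes lower in CaMKIIβ RIP than in Input 658 were protein coding, most of them outside the fixed lists. Of 25 mitochondrially encoded genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone; list adjusted p = 1.92e-11, and 0.269 with an estimated correlation). Among them the large ribosomal RNA mt-Rnr2 was at 169 ± 157 against 4523 ± 2021 CPM and the transfer RNA mt-Trnc at 5.6 ± 1.09 against 61.0 ± 5.77. Of 79 cytosolic ribosomal protein genes, 8 fell and 0 rose (11 and 0 adjusted over the list alone; list adjusted p = 2.7e-04, and 0.315 with an estimated correlation), with Rps27a at -1.84 ± 0.22 and Rpl7 at -0.99 ± 0.18. Of 80 nuclear-encoded genes of oxidative phosphorylation, 11 fell and 2 rose (20 and 3 adjusted over the list alone; list adjusted p = 9.17e-05, and 0.269 with an estimated correlation), with Atp5j at -1.48 ± 0.21, Atp5md at -1.14 ± 0.17 and Uqcrc1 at 0.71 ± 0.11. Of 21 neuronal and nuclear long noncoding RNAs, 8 fell and 0 rose (8 and 1 adjusted over the list alone; list adjusted p = 6.54e-06, and 0.269 with an estimated correlation), among them the imprinted Meg3 at 199 ± 14.6 against 348 ± 13.7 CPM and the X-linked Firre at 44.4 ± 3.81 against 87.9 ± 5.6. Over 1290 long noncoding RNA genes, 19 were lower and 1 higher over all genes tested, and 0 were past the threshold when adjusted over long noncoding RNA genes alone. The higher one was B930095G15Rik (ENSMUSG00000085133.2, chromosome 14, 121248706 to 121253971), at 110 ± 8.89 against 71.8 ± 3.31 CPM, a log2 fold change of 0.61 ± 0.13. The largest falls were those of 9630013A20Rik (-2.22 ± 0.37), 2410021H03Rik (-1.83 ± 0.39), E430024I08Rik (-1.66 ± 0.35) and Gm20045 (-1.64 ± 0.31). Outside the lists the largest rises were those of smooth muscle myosin Myh11 (2.69 ± 0.28), filamin Flnc (2.61 ± 0.35) and complement C3 (5.64-fold), and Gm45871 was at -3.64 ± 0.87.

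Of 22095 genes tested, 1117 were higher and 751 lower in CaMKIIβ RIP than in Input. The balance turned with the replicate block (1986 higher and 2219 lower) and at a fold change of at least 2 (288 higher and 376 lower). Input has no replicate 3, so with the block CaMKIIβ RIP replicate 3 did not bear on the difference. With library size alone as the scaling 683 were higher and 1361 lower, the all-gene median shifted by -0.17, and Camk2b (0.36) and B930095G15Rik (0.45) no longer passed. Camk2b was also lost without CaMKIIβ RIP replicate 3 (0.51). Without CaMKIIβ RIP replicate 1 the test called 0 genes (4607 at an unadjusted p under 0.05) and without CaMKIIβ RIP replicate 2 it called 4089, with 0 and 66 long noncoding RNA genes. Without Input replicate 1 or 2 it called 845 and 400 genes, 7 and 5 of them long noncoding, in fits where the spread came from the RIP libraries alone, so that these falls do not show dependence on a single Input library. DESeq2 called 3448 genes, the fit without a count filter 2866 and the fit of all 8 libraries 3833.

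**Figure D3:**
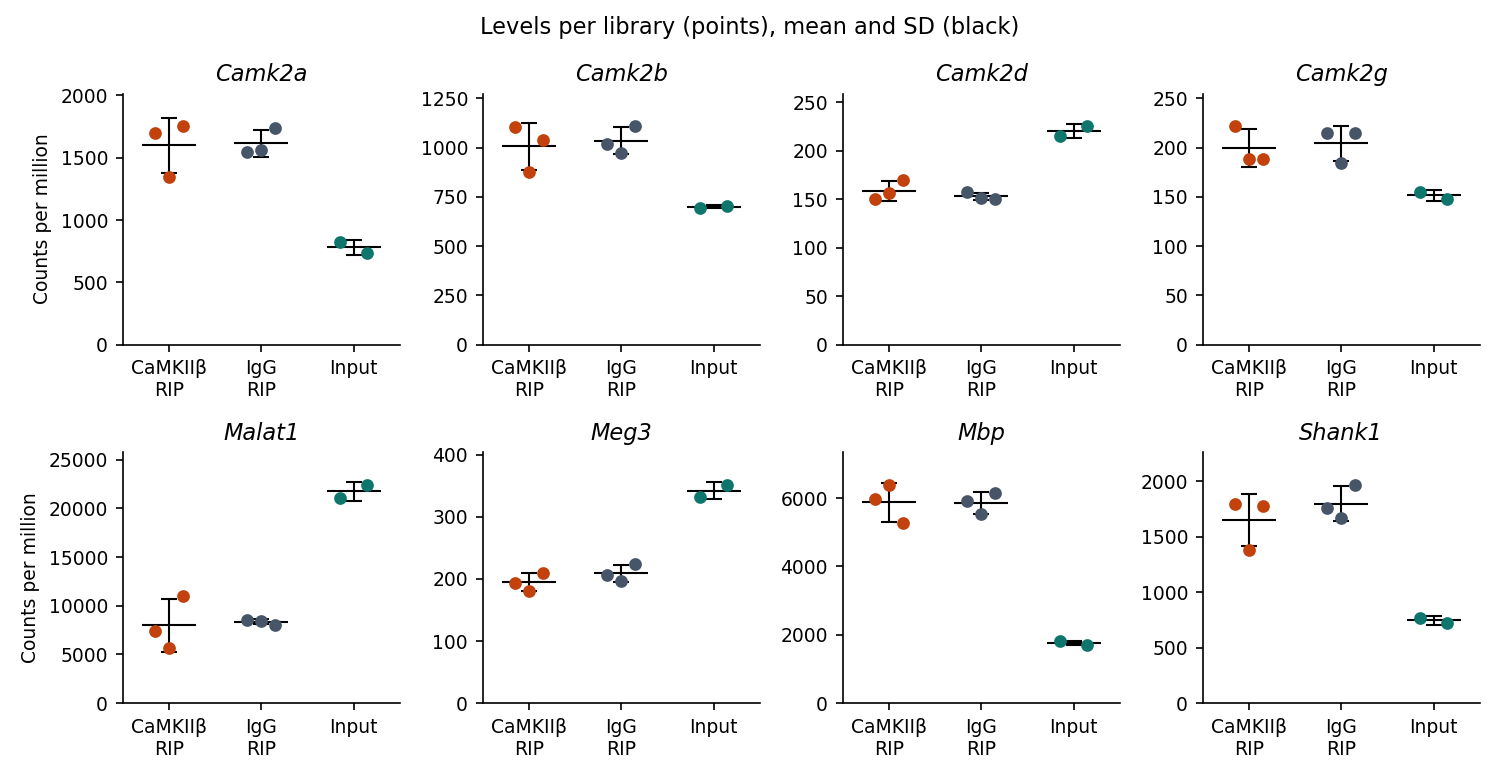
CPM, scaled over all 8 libraries (y axis), in each library (points) of CaMKIIβ RIP, IgG RIP and Input for 8 genes, with the group mean and SD in black. The points of the 2 antibodies overlap for each of these genes, and Input is lower for Camk2a, Camk2b, Camk2g, Mbp and Shank1 and higher for Camk2d, Malat1 and Meg3.

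IgG RIP against Input gives the background of the method, that is, which RNAs were at a higher or lower scaled level with the control antibody than in Input. Mbp rose 3.46-fold, from 1746 ± 63.4 to 6045 ± 317 CPM (SD, n = 2 Input and n = 3 RIP, as in the rest of this comparison), and Bsn rose 2.5-fold, from 791 ± 18.7 to 1980 ± 144. Malat1 (ENSMUSG00000092341.3), an abundant nuclear long noncoding RNA, was 2.51-fold lower, at 8612 ± 280 against 21596 ± 977 CPM. The cytochrome b transcript mt-Cytb was 4.63-fold lower, at 263 ± 7.76 against 1219 ± 14.7.

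Among synaptic genes, Camk2a (2.15-fold, from 775 ± 58.8 to 1666 ± 109 CPM), Camk2b (log2 fold change 0.62 ± 0.06, SE) and Camk2g (0.49 ± 0.07) rose and Camk2d fell (-0.47 ± 0.06), with the same calls when adjusted over the list alone and a list adjusted p of 0.0267 (0.303 with an estimated correlation). Of 19 postsynaptic density scaffold genes, 16 rose and 2 fell, over all genes and adjusted over the list alone (list adjusted p = 5.45e-13, and 0.169 with an estimated correlation), with Shank1 at 1.33 ± 0.07 and Homer1 at -0.49 ± 0.08. Dendritically localized mRNAs gave 15 higher and 1 lower of 20, both ways of adjusting (list adjusted p = 9.67e-16, and 0.169 with an estimated correlation), with Kif1a at 1.68 ± 0.06 and Itpr1 at 1.36 ± 0.06. Ionotropic glutamate receptors gave 9 higher and 3 lower of 15, both ways of adjusting (list adjusted p = 0.00253, and 0.169 with an estimated correlation), with Grin1 at 1.02 ± 0.08, Grik5 at 0.82 ± 0.07, Gria2 at -0.85 ± 0.07 and Gria3 at -0.42 ± 0.07. Presynaptic vesicle genes gave 11 higher and 3 lower of 18, both ways of adjusting (list adjusted p = 6.59e-04, and 0.362 with an estimated correlation), with the release factor Unc13a at 0.81 ± 0.07 and the membrane fusion protein Snap25 at -0.37 ± 0.05. Astrocyte markers gave 11 higher and 0 lower of 12, both ways of adjusting (list adjusted p = 1.37e-10, and 0.0704 with an estimated correlation), with Slc1a2 up 2.83-fold and Gfap at 1.20 ± 0.07. Oligodendrocyte lineage markers gave 7 higher and 5 lower of 15, both ways of adjusting (list adjusted p = 0.00884, and 0.169 with an estimated correlation), with Mobp at 1.35 ± 0.06 and Mog at -0.71 ± 0.09. With library size alone as the scaling, the median of the oligodendrocyte list turned from 0.09 to -0.14 and its adjusted p became 0.0693, and that of the subunits became 0.1.

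Of 26 mitochondrially encoded genes, 20 were lower and 0 higher in IgG RIP than in Input, both ways of adjusting (list adjusted p = 1.95e-21, and 0.0704 with an estimated correlation), with mt-Nd6 at -2.25 ± 0.08 and mt-Rnr2 at -5.58 ± 0.63. Of 79 cytosolic ribosomal protein genes, 47 fell and 8 rose (49 and 10 adjusted over the list alone; list adjusted p = 5.14e-07, and 0.324 with an estimated correlation), with Rplp1 at -1.78 ± 0.14, Rpl9 at -1.45 ± 0.13, Rpl29 at 0.79 ± 0.09 and Rpsa at 0.63 ± 0.07. Of 81 nuclear-encoded genes of oxidative phosphorylation, 42 fell and 8 rose (45 and 8 adjusted over the list alone; list adjusted p = 7.51e-08, and 0.321 with an estimated correlation), with Cox7b at -1.35 ± 0.11 and Ndufab1 at -1.31 ± 0.11. Blood markers gave 3 lower and 0 higher of 7, both ways of adjusting (list adjusted p = 0.00884, and 0.169 with an estimated correlation), with Hbb-bs at -1.07 ± 0.08 and the α-globin Hba-a1 at -0.97 ± 0.11. Neuronal and nuclear long noncoding RNAs gave 13 lower and 1 higher of 22, both ways of adjusting (list adjusted p = 2.75e-05, and 0.129 with an estimated correlation), with the neuronal transcript Snhg11 at -0.89 ± 0.06 and the imprinted Peg13 at 0.53 ± 0.07. Small nucleolar RNA host genes gave 9 lower and 0 higher of 14 (13 and 0 adjusted over the list alone; list adjusted p = 0.00884, and 0.324 with an estimated correlation), with Gas5 at -0.56 ± 0.11 and Snhg6 at -1.43 ± 0.28. Over 1322 long noncoding RNA genes, 159 were lower and 55 higher (108 and 37 when adjusted over long noncoding RNA genes alone). The largest falls were those of Gt(ROSA)26Sor (-3.41 ± 0.46), the dendritic RNA Bc1 (-1.99 ± 0.23), C230037L18Rik (-1.94 ± 0.43) and BC002059 (-1.90 ± 0.31), and the largest rises those of A930029G22Rik (1.39 ± 0.30), 1700012D16Rik (1.36 ± 0.37), Gm33280 (1.27 ± 0.39) and AI506816 (1.25 ± 0.19). Among other genes the largest rises were those of C3 (2.97 ± 0.23), the plasma protein Gc (2.94 ± 0.37) and Myh11 (2.74 ± 0.17), and besides mt-Rnr2 the largest falls were those of 4930447C04Rik (-3.07 ± 0.36) and Zfp825 (-2.90 ± 0.32).

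Of 22342 genes tested, 4483 were higher and 4170 lower in IgG RIP than in Input, and 620 were higher and 1451 lower at a fold change of at least 2. The common biological coefficient of variation was 0.115 here and 0.477 in CaMKIIβ RIP against Input. The larger counts of genes and list members called here thus do not show larger differences from Input. In the fit of all 8 libraries 3676 genes were called for IgG RIP and 3833 for CaMKIIβ RIP. With library size alone as the scaling 2714 were higher and 6345 lower, and the all-gene median shifted by -0.23. With a lone Input library the spread came from the RIP libraries alone. Without Input replicate 2 the test called 5659 genes in place of 8653 and mt-Rnr2 no longer passed, without Input replicate 1 or 2 the long noncoding RNA genes numbered 114 and 82 in place of 214, and the fit of all 8 libraries called 3676 genes, 36 of them long noncoding.

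**Figure D4:**
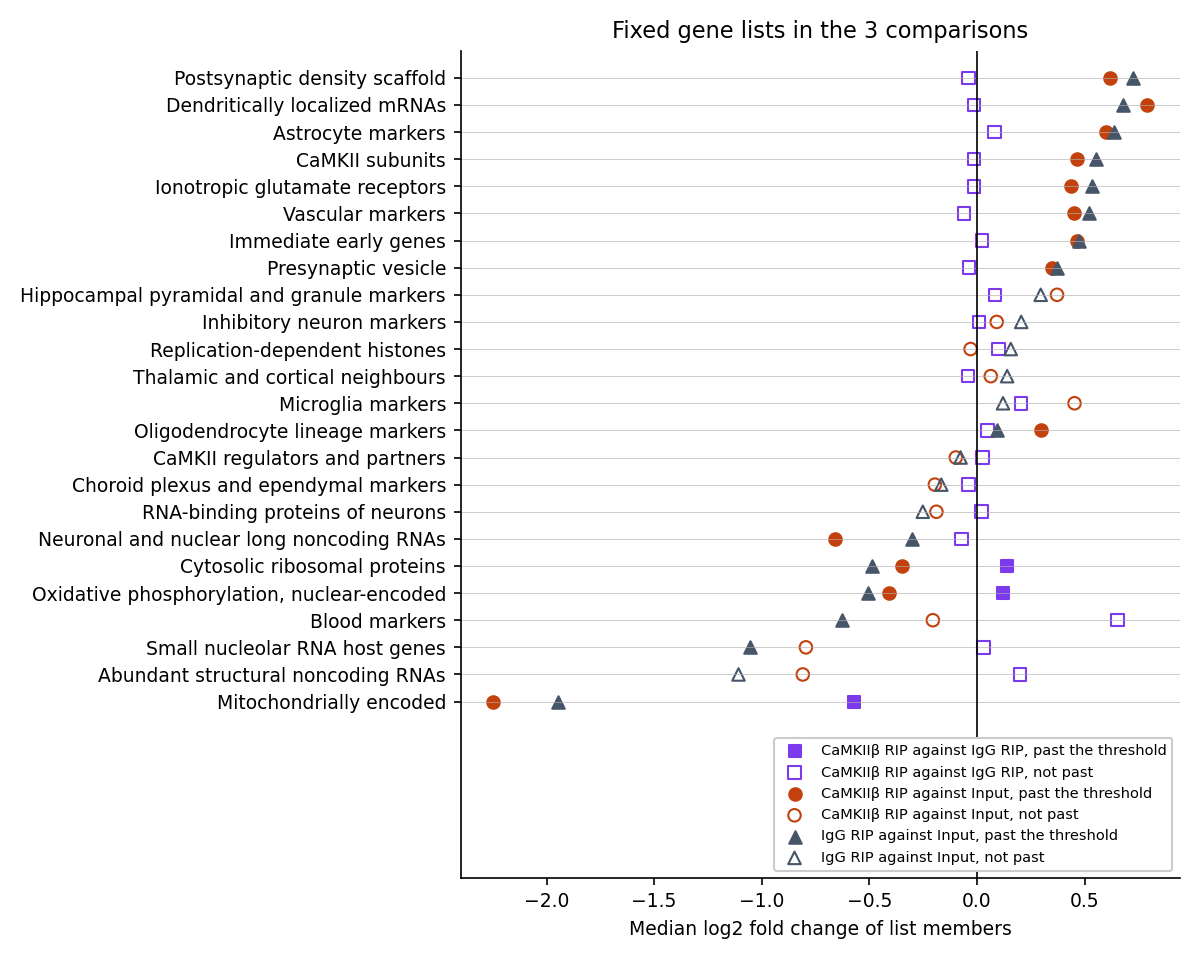
Median log2 fold change of the members (x axis) of the 24 fixed gene lists (y axis) in each of the 3 comparisons, with filled symbols for lists past the threshold in camera with the preset correlation. With an estimated correlation 0 lists passed in any comparison, and with library size alone as the scaling the medians of the inhibitory and thalamic and cortical lists turned negative in both comparisons with Input, as did those of the oligodendrocyte, microglia and histone lists in IgG RIP.

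The 2 antibodies were set side by side against the same Input. Of the 1868 genes called in CaMKIIβ RIP, 1117 were higher and 746 lower in both immunoprecipitates, and 0 genes were called in opposite directions. Independent calls would have given 231 and 145 shared genes. Since both comparisons used the same Input libraries, they were also simulated without any difference between groups, which gave 0.1 and 0 shared genes on average in 10 runs. With no gene changed, few genes are called at all, so these counts cannot show how much of the sharing came from the common Input. Each simulated gene also had the same spread in all libraries, unlike the real data. The covariance of the log2 fold changes across 15495 genes was 0.35, against 0.0961 in the simulation. Genes are not independent replicates. In a test added after these values were seen, each antibody was given an Input library of its own. With Input 2 for CaMKIIβ RIP and Input 1 for IgG RIP, 842 of 845 genes were called the same way (64.6 higher and 42.8 lower if independent; covariance 0.33 over 14875 genes), and the other way round 400 of 400 (39.6 and 19.3 if independent; covariance 0.322 over 14877 genes), with 0 in opposite directions. The spread in these fits came from the RIP libraries alone. Long noncoding RNA genes higher in CaMKIIβ RIP than in both IgG RIP and Input numbered 0 of 1106, which followed from the 0 genes that differed between the antibodies by edgeR, DESeq2 and limma-voom. At an unadjusted p under 0.05 in both comparisons edgeR gave 0. Only 10 genes were higher at that p against IgG RIP and 6 against Input, so independent calls would have given 0.0542. The simulation without any difference gave 5.6 on average. In it each gene had the same spread in all libraries, so 0 against 5.6 does not show a deficit.

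**Figure D5:**
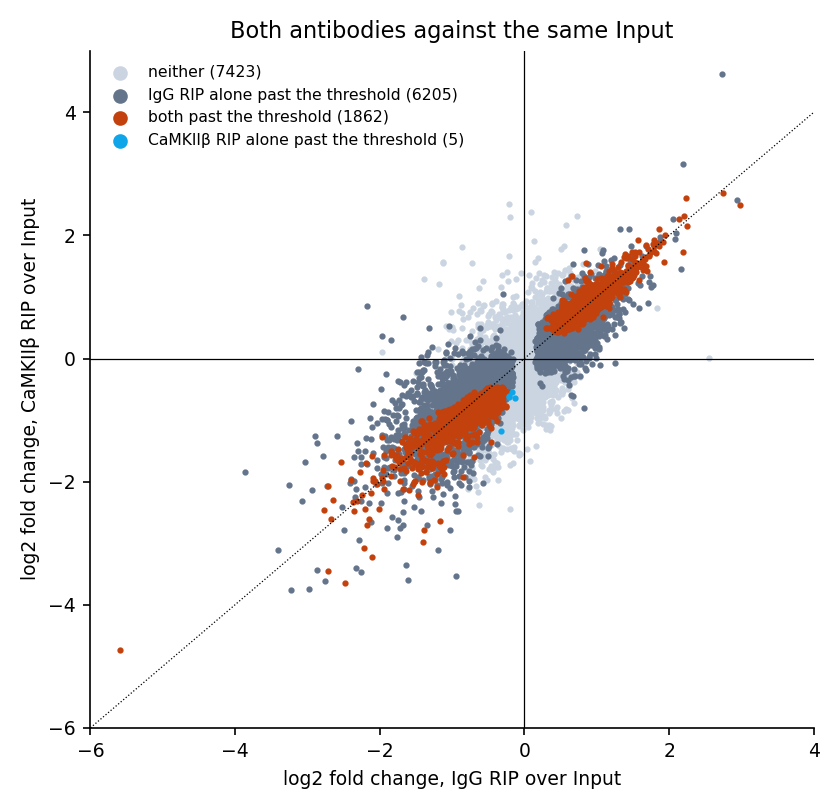
Log2 fold change of CaMKIIβ RIP over Input (y axis) against that of IgG RIP over the same Input (x axis) for 15495 genes; each point is a gene, coloured by the comparisons in which it passed the threshold, and the dotted line marks equal values. Both comparisons called 1862 of these genes, IgG RIP alone 6205 and CaMKIIβ RIP alone 5. The common biological coefficient of variation was 0.115 for IgG RIP and 0.477 for CaMKIIβ RIP against Input. The genes called for IgG RIP alone thus do not show RNAs that the CaMKIIβ antibody left out.

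Long noncoding RNA genes took 1.62% ± 0.397 of counts in CaMKIIβ RIP (SD, n = 3), 1.66% ± 0.0698 in IgG RIP (n = 3) and 3.49% ± 0.114 in Input (n = 2). Malat1 alone took 0.777% ± 0.258, 0.808% ± 0.0376 and 2.37% ± 0.106, and without Malat1 the long noncoding share was 0.842% ± 0.139, 0.856% ± 0.0358 and 1.12% ± 0.00745 (exact permutation p = 0.2 for CaMKIIβ RIP and 0.1 for IgG RIP against Input). Mitochondrially encoded genes took 0.555% ± 0.169, 0.792% ± 0.0573 and 2.0% ± 0.116, and protein-coding genes 93.3% ± 0.533, 93.0% ± 0.0672 and 88.9% ± 0.278. A two-sided exact permutation test gave p = 0.1 for long noncoding RNA, mitochondrial and protein-coding shares of either antibody against Input, which is the smallest p that 3 against 2 libraries allow. Between the antibodies the exact p was 0.9 for long noncoding RNA, 0.4 for protein-coding genes and 0.1, the smallest that 3 against 3 allow, for mitochondrially encoded genes. Small or structural RNA took 0.741% ± 0.331, 0.647% ± 0.0807 and 0.513% ± 0.0399 in CaMKIIβ RIP, IgG RIP and Input, with CaMKIIβ RIP replicate 2 at 1.12% (exact permutation p = 0.6 and 0.2 for CaMKIIβ RIP and IgG RIP against Input).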

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

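Between the antibodies the count of genes that differ was 0 under all settings, as was that of long noncoding RNA genes and of long noncoding RNA genes higher than in both IgG RIP and Input. The 3 lists past the threshold became 0 with an estimated correlation and ranged from 0 (without CaMKIIβ RIP replicate 2) to 5 (without CaMKIIβ RIP replicate 3). Camk2a was at 0.000564 with RLE scaling, 0.00231 with at least 10 counts in every library of a group and 0.000581 with DESeq2, at 0.05 without IgG RIP replicate 3, and from -0.0793 without CaMKIIβ RIP replicate 3 to 0.10 without replicate 2. Camk2b ranged from -0.10 to 0.0608 without CaMKIIβ RIP replicates 1 and 2, with 0.02 without IgG RIP replicate 3. Camk2g ranged from -0.11 without CaMKIIβ RIP replicate 1 to 0.012 without CaMKIIβ RIP replicate 3, with 0.01 also without CaMKIIβ RIP replicate 2 or IgG RIP replicate 1 or 3. Kcnq1ot1 ranged from -0.0879 to 0.18 and Snhg14 from -0.14 to 0.21, without CaMKIIβ RIP replicates 3 and 2. The signs of these values were not stable. In CaMKIIβ RIP against Input the 1868 genes became 2866 without a count filter, 3448 with DESeq2, 3833 in the fit of all 8 libraries, 4205 with the replicate block and 664 at a fold change of at least 2, and ranged from 0 to 4089 with a library left out. The 20 long noncoding RNA genes became 32 with DESeq2, 34 with limma-voom, 41 in the fit of all 8 libraries, 67 with the replicate block and 12 at a fold change of at least 2, and ranged from 0 to 66. The 13 lists became 0 with an estimated correlation. In IgG RIP against Input the 8653 genes became 3676 in the fit of all 8 libraries and 2071 at a fold change of at least 2, were 8931 with the replicate block, and ranged from 5659 to 9017. The 214 long noncoding RNA genes became 36 and 112 in the same 2 settings and ranged from 82 to 239, and the 15 lists became 0 with an estimated correlation. The histone list turned in sign in CaMKIIβ RIP against Input without CaMKIIβ RIP replicate 2 (adjusted p = 0.65) or Input replicate 1 (adjusted p = 0.921), with 0.435 without CaMKIIβ RIP replicate 3, and in IgG RIP against Input with library size alone (adjusted p = 0.806). Without mitochondrial and structural RNA the protein-coding share exceeded Input by 3.36 and 3.16 percentage points in CaMKIIβ RIP and IgG RIP, in place of 4.41 and 4.07, and the share of small or structural RNA differed by -0.0238 and -0.0236, in place of 0.228 and 0.134. The 1863 genes called the same way against Input in both immunoprecipitates became 842 and 400 when each antibody had an Input library of its own. Of the values of named genes with a library left out, 88 lost and 8 gained their call and 164 were unchanged in CaMKIIβ RIP against Input. In IgG RIP against Input 7 lost it and 413 were unchanged. Under the other settings 12 lost and 31 gained their call and 529 were unchanged in CaMKIIβ RIP, and 24 lost it and 900 were unchanged in IgG RIP. Libraries with the same number, compared within their groups, gave r = -0.00148, -0.0153 and -0.0887 between the antibodies. Pairs of the antibodies with unlike numbers reached 0.0588. For libraries with the same number r was 0.128 and 0.0704 for CaMKIIβ RIP with Input, and 0.0162 and 0.0193 for IgG RIP with Input. With 2 Input libraries, r with Input 1 is r with Input 2 with its sign turned. These values cannot exclude a shared source for any pair. Leaving out an Input library left a lone Input sample, with the spread taken from the RIP libraries alone. A match of at least 0.8 of the span gave 0, 19 and 171 long noncoding RNA genes, and removal of the length trend 1947 and 8671 genes against Input. A planned fit without the TEC biotype was not run, since the RefSeq table has no such class.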

Other observations

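Which of the gene groups below are described was chosen after the tests were seen. In IgG RIP against Input, immediate early genes gave 8 higher and 0 lower of 14 (10 and 0 adjusted over the list alone; list adjusted p = 0.0241, and 0.321 with an estimated correlation), with the transcription factor Jun at 0.81 ± 0.08 (log2 fold change ± SE, n = 3 RIP and n = 2 Input throughout) and the synaptic Arc at 0.97 ± 0.11. That list was lost with library size alone (3 higher and 3 lower, adjusted p = 0.0528), with the replicate block (adjusted p = 0.0578) and without IgG RIP replicate 3 (adjusted p = 0.0649). Vascular markers gave 7 higher and 2 lower of 12, both ways of adjusting (list adjusted p = 0.0114, and 0.169 with an estimated correlation), with the pericyte receptor Pdgfrb at 1.19 ± 0.09 and the transporter Slco1a4 at -0.85 ± 0.14. Inhibitory neuron markers gave 5 higher and 2 lower of 14 (list adjusted p = 0.0573), with the secreted protein Reln at 1.51 ± 0.06 and the calcium buffer Pvalb at -0.44 ± 0.08. Hippocampal pyramidal and granule markers gave 9 higher and 3 lower of 16 (list adjusted p = 0.145), with the transcription factor Zbtb20 at 0.56 ± 0.06 and the calcium buffer Calb1 at -0.70 ± 0.08. RNA-binding proteins of neurons gave 5 higher and 13 lower of 25 (list adjusted p = 0.0615), with the splicing factor Nova2 at 0.82 ± 0.08 and Fmr1, a regulator of synaptic translation, at -0.79 ± 0.08. CaMKII regulators and partners gave 5 higher and 7 lower of 17 (list adjusted p = 0.145), with calmodulin Calm2 at -0.75 ± 0.06 and Calm3 at 0.46 ± 0.07. Microglia markers gave 2 higher and 2 lower of 11 (2 and 3 with library size alone; list adjusted p = 0.654), choroid plexus and ependymal markers 2 and 2 of 10 (1 and 3 with library size alone; list adjusted p = 0.654), and thalamic and cortical markers 3 and 0 of 10 (list adjusted p = 0.0679), with Csf1r at 0.82 ± 0.09, Ttr at -0.58 ± 0.07 and Rorb at 0.85 ± 0.09. Structural noncoding RNAs gave 1 higher and 3 lower of 5 (list adjusted p = 0.172), with Rn7sk at 0.66 ± 0.09. Histones gave 3 higher and 5 lower of 35 (list adjusted p = 0.711), with a median of 0.16, a mean of -0.05 and a test pointing down.

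In CaMKIIβ RIP against Input, immediate early genes gave 2 higher and 0 lower of 14 (4 and 0 adjusted over the list alone; list adjusted p = 0.00357, and 0.207 with an estimated correlation), with Jun at 0.75 ± 0.13 and Arc at 0.82 ± 0.19. Vascular markers gave 3 higher and 1 lower of 12 (5 and 2 adjusted over the list alone; list adjusted p = 0.0101, and 0.315 with an estimated correlation), with the endothelial receptor Kdr up 1.99-fold (21.8 ± 1.64 to 43.4 ± 4.04 CPM, SD). Inhibitory neuron markers gave 3 higher and 2 lower of 14 (2 and 2 with library size alone; list adjusted p = 0.169), with a median of 0.09, a mean of -0.05 and a test pointing up, with Reln at 1.46 ± 0.14 and the GABA-synthesizing enzyme Gad2 at -0.47 ± 0.11. Hippocampal markers gave 3 higher and 1 lower of 16 (1 and 2 with library size alone; list adjusted p = 0.0773), with the kainate receptor Grik4 at 0.83 ± 0.15 and Calb1 at -0.68 ± 0.11. CaMKII regulators and partners gave 1 higher and 2 lower of 17 (0 and 5 with library size alone; list adjusted p = 0.396), with Calm2 at -0.78 ± 0.09. RNA-binding proteins of neurons gave 1 and 1 of 25 (1 and 6 with library size alone; list adjusted p = 0.254), thalamic and cortical markers 2 and 0 of 10 (list adjusted p = 0.0642), and microglia markers 1 and 0 of 11 (list adjusted p = 0.287). With 0 members past the threshold, the list adjusted p was 0.0582 for small nucleolar RNA host genes, 0.593 for structural noncoding RNAs, 0.755 for histones (median -0.03, test pointing up), 0.568 for blood markers and 0.606 for choroid plexus and ependymal markers. Between the antibodies the median, mean and test differed in sign for 8 lists with medians near 0: CaMKII subunits, regulators and partners, glutamate receptors, dendritic mRNAs, small nucleolar RNA host genes, and inhibitory, hippocampal and thalamic markers. The inhibitory list had a mean of -0.23, with its lowest member at -3.27.

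CaMKIIβ RIP replicate 2 stood apart, and the tests of its depth and of its molecules were chosen after the result was seen. Few RNA molecules behind its counts may explain this, since 28.3% of genes with 20 to 50 expected counts had 0 counts in it. If zeros are Poisson, genes with 10 to 20 expected counts had 22.3 counts per molecule there and 3.64 to 6.84 in the other RIP libraries. Lower depth did not account for it, since the other RIP libraries thinned to its depth still had at least 1.27 times as many genes with a count. Above 100 CPM its median absolute log2 ratio to IgG RIP was 0.20, the largest of the 6 RIP libraries (0.0467 to 0.129 in the others) and under the 0.3 set beforehand as the bound below which RNA of another tissue is unlikely.

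The test of recovery through CaMKIIβ and the tests of exon length were chosen after the result was seen. Of 1868 genes called in CaMKIIβ RIP against Input, 1863 were called the same way in IgG RIP against Input, so the differences from Input may reflect immunoprecipitation or library making and not CaMKIIβ. In IgG RIP exon length did not account for the whole shift of 3 lists, whose medians kept their sign with its trend removed. They went from -0.49 to -0.38 (ribosomal proteins), from -0.51 to -0.34 (oxidative phosphorylation) and from 0.72 to 0.66 (postsynaptic scaffolds). Bootstrap intervals (2000 draws) with the trend removed were -0.56 to -0.28, -0.60 to -0.20 and 0.25 to 0.83. Each interval held the median before removal, so a part played by exon length was not shown, though not excluded. Nor did exon length account for mitochondrially encoded genes (-1.95 to -2.07), dendritic mRNAs (0.68 to 0.81) or astrocyte markers (0.64 to 0.63). The same held for the list of neuronal and nuclear long noncoding RNAs (-0.30 to -0.48). Over all 1322 long noncoding RNA genes, 55 higher and 159 lower became 71 and 143 with the trend removed. In the 10 splits of the 6 RIP libraries into 3 and 3, 5 gave at least the 3 lists of the real split, with 5 lists in the highest other, so the list shifts between the antibodies could be chance, while for genes and long noncoding RNA genes the real count of 0 was matched by all 10 by construction and tells nothing.

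Cerebellar transcripts were noticed first in the tables, and the tests on genes not looked at before were written before those genes were read. Fat2 (3883 to 4793 CPM in RIP, 1470 to 1567 in Input), Cbln3 (620 to 756 over the 8 libraries) and Gabra6 (185 to 260 in RIP, 407 to 409 in Input) mark cerebellar granule cells but moved apart against Input, and the lowest library median of 7 further cerebellar transcripts was 20.1 CPM. Cerebellar RNA in every library may explain this, which is a hypothesis, since the labels give hippocampus. A part of the libraries alone would not give a highest over lowest median of 1.46, and wrong symbols are unlikely with a median shared span of 0.977. Telencephalic RNA was present too, with library medians of 12.7 to 15.7 CPM for 7 transcription factors, against 20.1 to 29.2 for the 7 further cerebellar transcripts. Library medians were 30.7 to 53.0 CPM for 5 hippocampal transcripts (Prox1 88.6 to 143, Neurod6 10.9 to 31.9) and 409 to 529 for the 9 cerebellar transcripts noticed first. These last 2 sets were picked from the same data, and medians of unlike genes do not measure the share of a tissue.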
